A study of Mus musculus with 6 samples.

How the data were processed

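Polyadenylated RNA was measured in 6 samples of bEnd.3, a mouse brain endothelial cell line transformed with polyoma middle T antigen. Titles in the labels gave 3 samples with a control short hairpin RNA (replicates 1, 2 and 3) and 3 with a hairpin against Npc1 (replicates 4, 5 and 6). A further label tag calls the control samples WT, while their titles call them shControl; the titles were used. The labels do not say whether the replicates of a group were separate cultures, or whether replicates 4, 5 and 6 carried the same hairpin, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, mRNA was enriched on oligo(dT) beads, fragmented, copied into double-stranded cDNA, ligated to adapters, amplified, circularised and sequenced from DNA nanoballs by combinatorial probe-anchor synthesis.

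The authors deposited 1 table with 15917 genes, each with an NCBI gene number and a symbol. It holds 6 columns of FPKM (fragments per kilobase of transcript and per 1e6 mapped fragments), which the authors rounded to 2 decimals. The deposited table also holds the authors' log2 ratio of knockdown to control and a p-value and q-value for it. The deposited q-values equalled a Benjamini-Hochberg adjustment of the deposited p-values to within a ratio of 0.992 to 1.01. The aligner, the counting program, the genome build, the annotation and the test behind the authors' p-values are not given in the sources used here, nor is whether the libraries kept strand, so reads of overlapping genes and of near-identical copies cannot be told apart. No read counts were used and the absolute depth is unknown. For transcripts of 300 to 3000 bases, FPKM values from 0.03 to 0.6 were multiplied by transcript length in kilobases. With the authors' own lengths, unrounded values and no shared fragments, the products would be whole multiples of the worth of 1 fragment. Here they can be so only roughly. In bins of 0.02 the most common product was 0.06 to 0.08 in each of the 6 libraries, so no difference in depth was seen beyond the width of that bin. Whole reads were not recovered. The FPKM values of a library summed to between 661950 and 757026.

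The values were analysed as log2(FPKM + 1) for the 10400 genes with a mean of at least 1 FPKM over the 6 samples. Fold changes are given on that scale, which understates the change of genes of low expression; ratios are ratios of the mean FPKM. Knockdown and control were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. For Npc1 an exact two-sided permutation test was added. The 30 lists of genes covered sterol and lipid metabolism, lysosomes and autophagy, interferon and inflammation, endothelial barrier, identity and signalling, matrix, cell cycle, stress, energy metabolism and markers of other cell types. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists with at least 5 tested members; camera with an estimated correlation and fry were run beside it. Values for the same 10400 genes were also simulated, with 200 genes changed. The test recovered 54% of genes changed 1.5-fold, 88% of those changed 2-fold and 98% of those changed 4-fold, and 5.06% of its calls were unchanged genes. Genes were simulated as independent, with the same spread in both groups, no trend with GC content and no library standing apart. These rates therefore need not hold for the measured values.

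The groups, the test, the lists and the rule for naming genes were fixed before the data were examined. The rule names Npc1; the 10 genes with the highest and the 10 with the lowest log2 fold change among those past the threshold whose groups do not overlap and whose higher group mean is at least 2 FPKM, without predicted, clone-named and pseudogenes; up to 4 members of each list with the smallest p; and a set of landmark genes of sterol, lysosomal, endothelial and interferon biology. Members of a list past the threshold may also be named in a count. Some genes that the rule names are not reported here. Transcript length and GC content came from the longest protein-coding transcript of each gene in a GENCODE mouse annotation, which need not be the one the authors used, matched by NCBI gene number; 98.5% of the tested genes had a value. As the table names no build, no coordinates are given.

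The alternatives fixed at the outset were other pseudocounts and filters on low values, scaling to TPM, by library median, by trimmed mean of M values or by quantiles, limma without the trend, with robust estimation or with sample weights, a fold threshold of 2, and each library left out in turn. Corrections for GC content and transcript length were added after seeing the data. They subtract from each library a spline of its deviations on GC content with 5 degrees of freedom, and so also centre the libraries; a version that keeps each library's level was run beside it. Ranges of adjusted p over all alternatives cover every setting run except the fold threshold, with estimated correlation and fry included for lists. They include the sample weights, whose estimation did not converge, so the low end of a range can come from that fit. Near-identical transcripts were found with BLAST 2.17.0 at an identity of at least 95% over at least 80% of the length. Figures were drawn with matplotlib 3.10.9.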

Results

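The mRNA of bEnd.3 brain endothelial cells carrying a hairpin against Npc1 was compared with that of cells carrying a control hairpin, with 3 libraries in each group. Npc1 encodes a membrane protein that moves cholesterol out of late endosomes and lysosomes. The comparison asked which transcripts differ when Npc1 is reduced in these cells. Between 13777 and 14146 genes had a value above 0 in a library, and the 10 most abundant genes held 7.60% to 8.85% of a library's summed FPKM.

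Npc1 (gene 18145) was measured first, as a check of the labels. Its FPKM was 6.31, 6.63 and 7.27 in control replicates 1, 2 and 3, and 0.45, 1.20 and 0.97 in knockdown replicates 4, 5 and 6. The knockdown libraries thus held 13.0% ± 5.70 (SD, n = 3) of the control mean. All 3 knockdown values lay below all 3 control values, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 samples allow. In limma the log2 fold change was -2.07 (SE 0.16, adjusted p = 0.000723).

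Genes of cholesterol synthesis and uptake rose together in the knockdown. Of the 24 measured members of the list of SREBP2 targets, 22 rose and 0 fell, with a median log2 fold change of 1.17. Fdps (gene 110196), the farnesyl diphosphate synthase gene, rose from 27.2 ± 3.34 to 165 ± 32.4 FPKM (SD, n = 3 per group), a ratio of 6.06 (log2 2.55, SE 0.15, limma adjusted p = 0.000290). Msmo1, a sterol-C4-methyl oxidase, rose from 16.8 ± 0.357 to 84.9 ± 2.42 FPKM. Sqle, the squalene epoxidase, rose 3.14-fold. Idi1 and Fdft1 rose 3.60-fold and 3.52-fold. The transcription factor gene Srebf2 rose 3.02-fold and Insig1, whose product retains SREBP in the endoplasmic reticulum, 3.24-fold. Hmgcs1 rose 2.86-fold. The list stood apart from other genes in camera (adjusted p = 1.25e-18) and with an estimated correlation (adjusted p = 0.0183); adjusted over the list alone, 23 members rose.

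Of 17 targets of SREBP1 in fatty acid synthesis, 9 rose and 1 fell (median log2 0.41), as they did when adjusted over the list alone. The 1 that fell passed only with all 3 control replicates and knockdown replicate 6 included; without any 1 of these libraries 7 rose and 0 fell. Fads2, a fatty acid desaturase, rose 2.57-fold, from 25.4 ± 0.916 to 65.3 ± 6.52 FPKM (SD, n = 3 per group). Lpin1 rose 2.19-fold, Fads1 1.60-fold and Scd2 1.41-fold. The camera adjusted p was 0.0012, and the call was lost with an estimated correlation (adjusted p = 0.264).

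Genes of sterol efflux did not move as a group in camera (adjusted p = 0.965), while fry, which does not compare a list with other genes, called the list lower (adjusted p = 0.00367, with a range of 0.00367 to 1 over all alternatives). Abcg1, an exporter of sterols and a target of the liver X receptors, fell from 5.16 ± 0.171 to 0.493 ± 0.0777 FPKM (SD, n = 3 per group), a log2 fold change of -2.05 (SE 0.08, limma adjusted p = 8.32e-05). Scarb1, a lipoprotein receptor, rose 1.78-fold, and the other 4 of the 6 measured members did not pass, among them Lpcat3 (log2 0.20) and Arl4c (log2 0.15). Abca1 was too low to be tested, with 0.333 ± 0.0351 FPKM in the control and 0.0667 ± 0.0208 in the knockdown (SD, n = 3); the authors' deposited table gives it a log2 ratio of -2.33 and q = 1.8e-08. The median (0.0836) and mean (-0.19) log2 fold change of the list differed in sign. Adjusted over the list alone 2 rose and 1 fell, and 2 rose without knockdown replicate 4. Of 15 measured genes of intracellular sterol transport, 3 rose and 0 fell, 5 and 0 adjusted over the list alone (camera adjusted p = 0.14). Without knockdown replicate 4 the adjusted p was 0.0428, within a range of 0.00367 to 0.276 over all alternatives, and 8 rose; 1 rose without control replicate 1, 2 or 3 or knockdown replicate 6. Npc2, the soluble lysosomal partner of Npc1, rose 1.91-fold, from 55.6 ± 3.52 to 106.0 ± 16.4 FPKM.

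**Figure D1:**
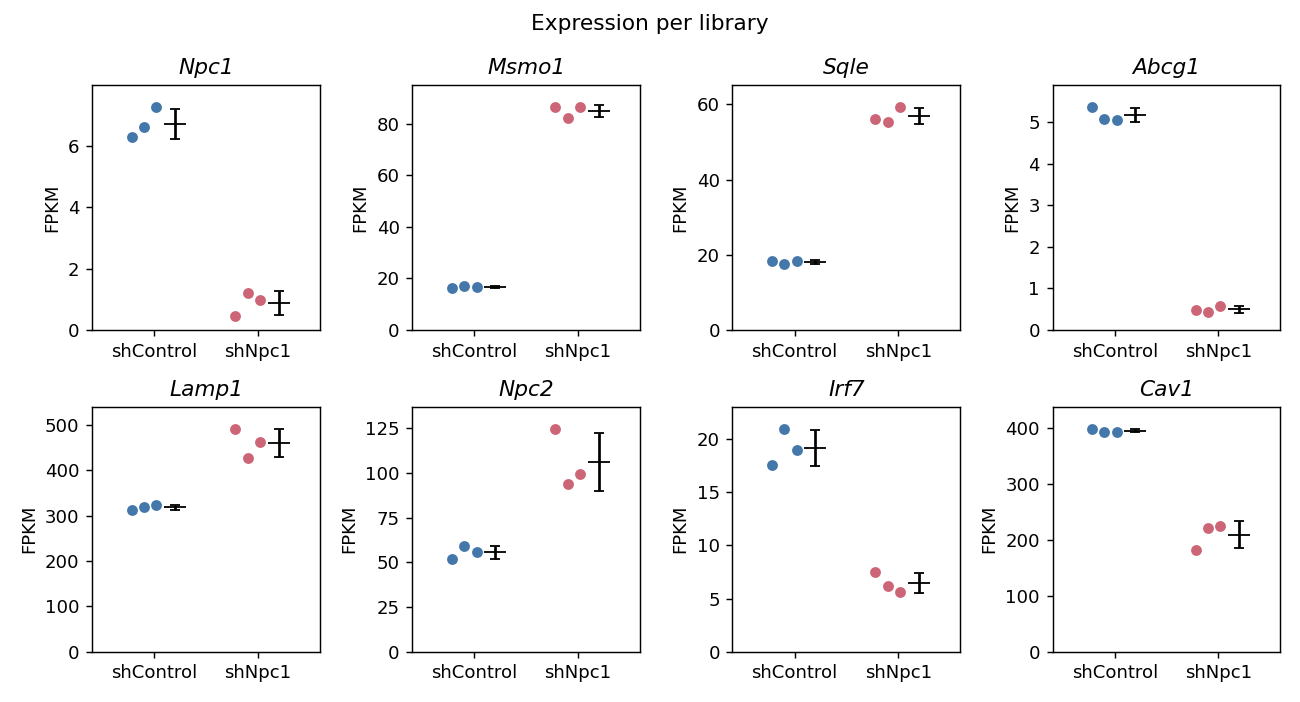
FPKM (vertical axes, from 0) of 8 genes in the 3 shControl and 3 shNpc1 libraries; points are libraries, and bars beside them the mean with 1 SD. Npc1, Abcg1, Irf7 and Cav1 lie lower and Msmo1, Sqle, Lamp1 and Npc2 higher in all 3 knockdown libraries than in any control library.

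Lysosomal genes rose with smaller folds. Of the 45 genes of the list, all of them measured, 31 rose and 0 fell (median log2 0.41). Tpp1, a lysosomal peptidase gene, rose 1.53-fold, from 71.8 ± 2.21 to 110 ± 2.66 FPKM (SD, n = 3 per group). Mcoln1, a lysosomal ion channel gene, rose from 13.9 ± 0.356 to 23.7 ± 1.28 FPKM, and the membrane protein gene Lamp1 rose 1.45-fold. Ctsd, the cathepsin D gene, rose 1.59-fold (limma adjusted p = 0.0108); its adjusted p was 0.0573 without control replicate 1 and 0.0538 without control replicate 3, the range over all alternatives being 9.48e-07 to 0.0573. The camera adjusted p of the list was 9.14e-14, and the call was lost with an estimated correlation (adjusted p = 0.264); adjusted over the list alone, 35 members rose. Without control replicate 1, 2 and 3 the members that rose were 16, 18 and 17, and without knockdown replicate 6 they were 19, with 0 falling. Of 27 autophagy genes 8 rose and 0 fell (camera adjusted p = 0.000514; adjusted p = 0.264 with an estimated correlation), and 12 and 0 adjusted over the list alone. Without control replicate 1, 2 and 3 and knockdown replicate 6 they were 3, 2, 3 and 2. Uvrag rose 1.45-fold and Flcn 1.48-fold. Sqstm1, an autophagy receptor gene, reached a ratio of 1.30 (limma adjusted p = 0.0459), which was not kept without control replicate 1 (adjusted p = 0.171), 2 (0.102) or 3 (0.151) or without knockdown replicate 6 (0.106), nor without a filter (0.0724), with median centring (0.0999), with trimmed mean of M values (0.069), without the trend (0.0517) or with robust estimation (0.0501). Of 18 sphingolipid genes 6 rose and 3 fell, also when adjusted over the list alone, and 0 fell without control replicate 1, 2 or 3 or knockdown replicate 6 (camera adjusted p = 0.265, fry adjusted p = 0.000681 in the direction higher, 0.000681 to 0.529 over all alternatives); B4galt5 rose 1.72-fold and the acid ceramidase gene Asah1 1.79-fold.

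Interferon-stimulated genes fell. Of 32 measured members 19 fell and 0 rose (median log2 -0.55; camera adjusted p = 2.27e-12, adjusted p = 0.0183 with an estimated correlation); adjusted over the list alone, 21 fell. Without control replicate 1 or 3 the members that fell were 12. Irf7, a transcription factor of the interferon response, fell to a ratio of 0.336, with 6.44 ± 0.943 FPKM left (SD, n = 3), a log2 fold change of -1.44 (SE 0.11, limma adjusted p = 0.000738). Ifi44 fell from 6.27 ± 1.23 to 1.15 ± 0.348 FPKM, and Isg15, a ubiquitin-like modifier, from 24.1 ± 1.79 to 11.7 ± 2.11 FPKM. Oasl2 had a ratio of 0.483 and Rtp4 of 0.599. Ifi27l2a and Trim30a, outside the list, were among the 10 genes with the lowest log2 fold change, with ratios of 0.188 and 0.189.

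Of 17 measured genes of NF-kB inflammation and leukocyte adhesion, 4 rose and 1 fell (camera adjusted p = 0.965; the median was -0.0219 and the mean 0.0039, with the test's direction higher). Adjusted over the list alone 5 rose and 3 fell; 2 rose without control replicate 1 or knockdown replicate 6, and 2 fell without knockdown replicate 5. The chemokine gene Ccl5 fell from 78.2 ± 4.61 to 28.4 ± 0.803 FPKM, while Tnfaip2 rose 1.57-fold and the P-selectin gene Selp 1.30-fold. Vcam1 (log2 0.12, adjusted p = 0.38) and Icam1 (log2 0.37, adjusted p = 0.074) did not pass; after a GC correction, chosen after seeing the data, Vcam1 passed as higher (log2 0.25, adjusted p = 0.00792, 0.000335 to 0.64 over all alternatives).

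Among genes of the endothelial barrier, those of caveolae fell in part. Cav1, the caveolin that coats caveolae, fell from 395.5 ± 2.91 to 209.6 ± 24.5 FPKM (SD, n = 3 per group), a log2 fold change of -0.92 (SE 0.09, limma adjusted p = 0.00204). Cav2 and Ehd4 fell to ratios of 0.571 and 0.654, and the other 8 of the 11 measured members did not pass, among them Plvap (log2 -0.011); after the GC correction 6 members fell, Plvap among them (log2 -0.20, adjusted p = 0.0164, 0.006 to 0.962 over all alternatives). The camera adjusted p of the caveolae list was 0.0454; it was 0.264 with an estimated correlation, 0.0882 without control replicate 2, 0.183 without knockdown replicate 5 and 0.0757 without knockdown replicate 6, with a range of 0.000185 to 0.264 over all alternatives. The same 3 passed when adjusted over the list alone, and 5 fell without knockdown replicate 4. Of 13 junction genes 0 rose and 1, Cldn12, fell, also when adjusted over the list alone (ratio 0.645; camera adjusted p = 0.192). After the GC correction, chosen after seeing the data, 0 junction genes rose and 6 fell, and the adjusted p of the list was 0.0305 (0.0282 to 0.744 over all alternatives), and without knockdown replicate 4 the junction genes that rose and fell were 1 and 3. Cldn12 had an adjusted p of 0.0533 without control replicate 1 and 0.0538 without control replicate 3. Cdh5 (log2 -0.12), Pecam1 (log2 -0.14) and Tjp1 (log2 -0.17) did not pass; after the GC correction Cdh5 (log2 -0.22, adjusted p = 0.0245) and Pecam1 (log2 -0.20, adjusted p = 0.0291) passed as lower, with ranges of 0.0013 to 0.407 and 0.000544 to 0.391 over all alternatives. Cldn5 was listed at 0 in all 3 control libraries and at 0, 0 and 0.05 in the knockdown libraries. Mfsd2a was listed at 0 in all 3 controls and at 0, 0.03 and 0.03 in the knockdown libraries. A listed 0 need not mean that the mRNA was absent, since the counting program and annotation are not given. Ocln and Abcb1a had means under 1 FPKM in both groups and were not tested. Of 14 transporters and receptors of the blood-brain barrier 5 rose and 1 fell (camera adjusted p = 0.14; 0.0491 without knockdown replicate 4). Slc3a2 rose 1.51-fold. Adjusted over the list alone they were 5 and 1; without control replicate 1, 2 or 3 or knockdown replicate 6 they were 1 and 0, and 3 rose without knockdown replicate 5. Over all alternatives the adjusted p of the list was 0.0128 to 0.339. The glucose transporter gene Slc2a1 had a ratio of 1.20 and an adjusted p of 0.0424, which was not kept without control replicate 1 (0.167), 2 (0.132) or 3 (0.137) or without knockdown replicate 6 (0.0968), nor without a filter (0.0524), without the trend (0.0534), with median centring (0.114), trimmed mean of M values (0.0724) or quantiles (0.0539), or after the GC correction (0.0545), also with length added (0.0547).

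Of 28 endothelial identity genes 3 rose and 4 fell, 5 and 6 adjusted over the list alone (camera adjusted p = 0.078; 0.000659 to 0.264 over all alternatives). The list was called lower without knockdown replicate 4 (adjusted p = 0.0248), with TPM (0.0263), with quantiles (0.0192) and after the GC correction (0.00147), where 2 rose and 13 fell. Without knockdown replicate 4, 5 rose and 11 fell; without control replicate 1, 2 or 3, 0 rose and 1 fell, and without knockdown replicate 6, 0 and 2. Sox18 fell to a ratio of 0.650. In the list of angiogenesis, VEGF and Notch genes, 6 of 22 rose and 6 fell, 8 and 6 adjusted over the list alone (camera adjusted p = 0.718). Those that rose and fell were 2 and 3 without control replicate 1 or 3, 3 and 4 without control replicate 2, and 3 and 3 without knockdown replicate 6; Jag1, Notch4 and Nrarp were among those that lost their call, with adjusted p of 0.103, 0.0592 and 0.0718 without control replicate 1, 0.0975, 0.0634 and 0.0784 without control replicate 3, and 0.0815, 0.0509 and 0.0546 without knockdown replicate 6. Without control replicate 2, Jag1 (0.0576) and Nrarp (0.0742) did so. The members that fell were the Notch ligand genes Dll4, Dll1 and Jag1, the receptor gene Notch4 and the Notch targets Hes1 and Nrarp. Other Notch genes of the list were not among them, and 10 of the 22 members did not pass. Dll4 fell from 4.06 ± 0.0794 to 1.49 ± 0.0624 FPKM and Hes1 from 13.1 ± 0.249 to 5.70 ± 0.331 (SD, n = 3 per group). Among those that rose, Angpt2, an antagonist of the Tie2 receptor, went from 61.6 ± 2.81 to 140.5 ± 11.9 FPKM and Unc5b rose 2.15-fold. In the list of TGF-beta and endothelial-mesenchymal transition, 4 of 18 rose and 4 fell, 4 and 5 adjusted over the list alone (camera adjusted p = 0.201, fry adjusted p = 0.02 in the direction lower, 0.02 to 0.568 over all alternatives); without control replicate 1 and 3 those that fell were 2 and 1. Acta2, smooth muscle actin, rose from 1.44 ± 0.214 to 8.39 ± 2.68 FPKM, and Tgfbr2, a TGF-beta receptor gene, fell from 32.4 ± 0.390 to 13.9 ± 0.823. Of 11 genes of the Wnt list 1 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.14; 0.0455 after the GC correction, where 0 rose and 6 fell, and 0.0364 to 0.326 over all alternatives). None passed without control replicate 1, 2 or 3, and 1 rose and 1 fell without knockdown replicate 6. Of 18 matrix genes 2 rose and 2 fell, 2 and 3 adjusted over the list alone (camera adjusted p = 0.892; the median was 0.03 and the mean -0.0047). Without control replicate 1 or 3, 1 matrix gene rose and 0 fell, without control replicate 2 or knockdown replicate 6, 1 and 1, and those that fell were 4 without knockdown replicate 4 and 1 without knockdown replicate 5.

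Some targets of NRF2, ATF4 and p53 rose. Of 15 targets of NRF2, the transcription factor of the oxidative stress response, 9 rose and 0 fell (camera adjusted p = 3.5e-05; adjusted p = 0.264 with an estimated correlation), and 10 rose and 1 fell adjusted over the list alone. Without control replicate 1 or 2 or knockdown replicate 6, 5 rose, and 1 fell without knockdown replicate 5. Hmox1, the heme oxygenase gene, rose from 276.4 ± 7.06 to 855.4 ± 91.9 FPKM and Nqo1 from 23.2 ± 1.34 to 75.4 ± 4.97 (SD, n = 3 per group). Of 15 targets of ATF4 8 rose and 0 fell (camera adjusted p = 0.000816; adjusted p = 0.276 with an estimated correlation); Chac1 rose 2.19-fold, Atf5 1.94-fold and Ddit3 1.63-fold. Adjusted over the list alone 9 targets of ATF4 rose, and 5 rose without control replicate 2 or 3. Of 16 targets of p53 5 rose and 0 fell (camera adjusted p = 0.0366; adjusted p = 0.264 with an estimated correlation). That call was not kept without control replicate 2 (adjusted p = 0.0764) or without knockdown replicate 5 (0.0516) or 6 (0.0638), and ranged from 0.00197 to 0.264 over all alternatives. Adjusted over the list alone 7 targets of p53 rose; without control replicate 1, 2 and 3 they were 3, 2 and 2, and without knockdown replicate 4 and 6 they were 8 and 3. Zmat3 rose 1.34-fold. Of 15 genes of endoplasmic reticulum chaperones and the unfolded protein response 1 rose, Herpud1, 1.61-fold, also when adjusted over the list alone (camera adjusted p = 0.718, fry adjusted p = 0.0198 in the direction higher, 0.0198 to 0.866 over all alternatives); 3 rose and 2 fell without knockdown replicate 4, and 2 fell without knockdown replicate 5. Of 26 genes of glycolysis and hypoxia 3 rose and 2 fell, 4 and 3 adjusted over the list alone (camera adjusted p = 0.567, 0.00316 to 0.942 over all alternatives). Those that rose and fell were 0 and 0 without control replicate 1 or 3, 1 and 1 without control replicate 2, 0 and 1 without knockdown replicate 6, 4 and 6 without knockdown replicate 4 and 4 and 1 without knockdown replicate 5. Of 39 nuclear genes of oxidative phosphorylation 0 passed in limma, also when adjusted over the list alone, and 1, Ndufa4, had an unadjusted p under 0.05 (0.0248). The camera adjusted p of that list was 0.265; it was 0.0148 without knockdown replicate 5 and 0.000824 to 0.88 over all alternatives. Of 35 cell cycle genes 1 fell, the cyclin gene Ccne2, from 15.3 ± 1.40 to 4.63 ± 0.833 FPKM (camera adjusted p = 0.718; the median was 0.0349 and the mean -0.057). The same count was found adjusted over the list alone, and 1 rose and 2 fell without knockdown replicate 4 or 5. Mki67 did not pass (log2 -0.31, adjusted p = 0.425). None of the 13 mitochondrially encoded mRNAs was analysed here.

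Few markers of other cell types reached 1 FPKM. None of the fibroblast markers did. Among pericyte and smooth muscle markers Acta2 rose and Mcam did not pass (log2 0.093). Among astrocyte markers Aldh1l1 rose 4.81-fold, to 5.29 ± 0.508 FPKM, and Gja1 fell from 65.6 ± 1.97 to 27.9 ± 3.17. The macrophage marker Cd68, also a lysosomal membrane protein, rose 2.12-fold. The neurofilament gene Nefl had a ratio of 1.24 and an adjusted p of 0.0211, which lay between 0.0844 and 0.105 without control replicate 1, 2 or 3 or knockdown replicate 6 and was 0.0639 with median centring. Each of the same markers passed when adjusted over the list alone.

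**Figure D2:**
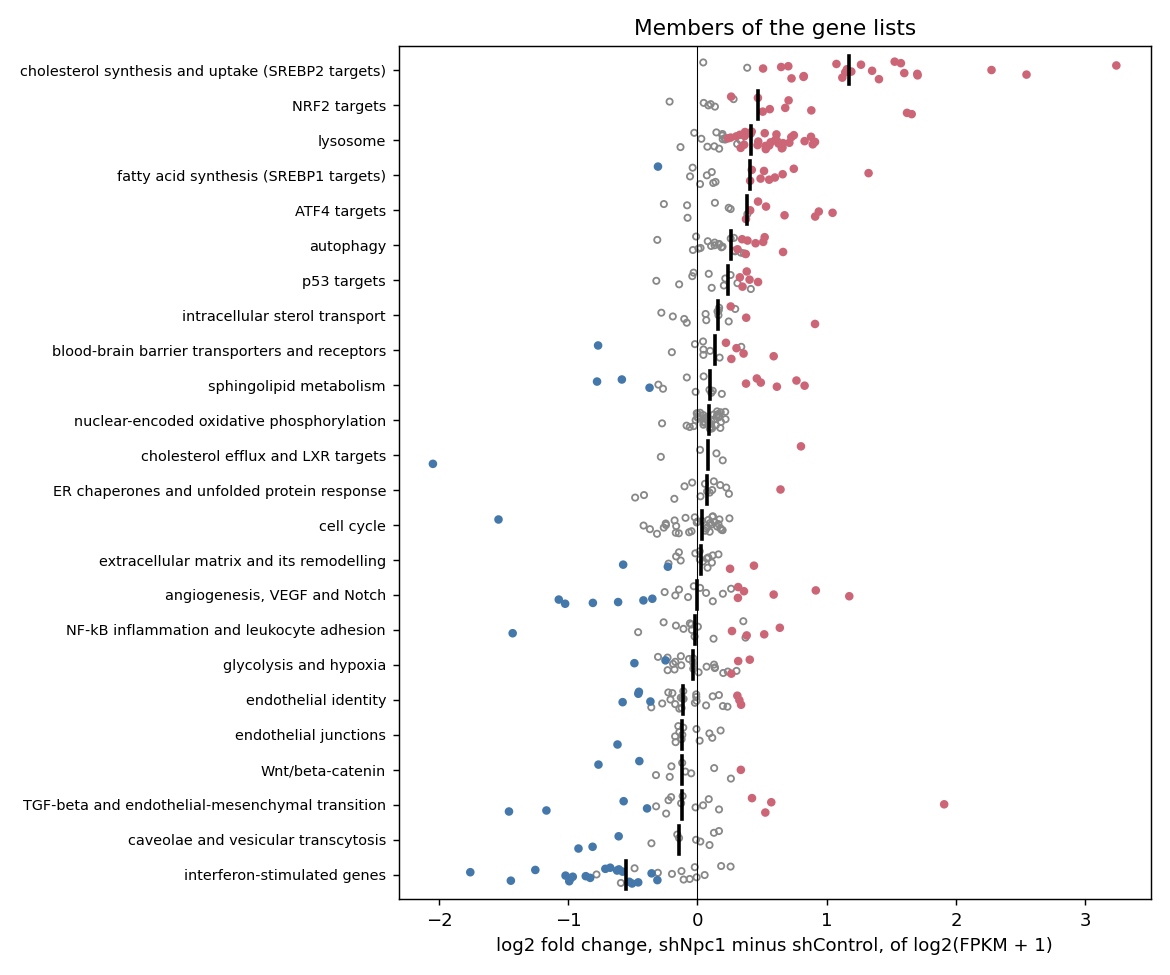
Log2 fold change of log2(FPKM + 1), knockdown minus control (horizontal axis), of the tested members of the 24 lists with at least 5 of them; filled points passed an adjusted p of 0.05 (red higher, blue lower), open points did not, and black bars are list medians. The medians run from -0.55 for interferon-stimulated genes to 1.17 for SREBP2 targets.

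The other genes at the ends of the ranking were Slc14a1, a urea transporter gene, which rose 6.03-fold, and Plekha3, Spp1, Stfa3 and Stfa2, which fell to ratios of 0.307, 0.290, 0.292 and 0.301. Sprr2a2 fell from 15.8 ± 0.985 FPKM to 0, 3.22 and 5.51 in the knockdown libraries (limma adjusted p = 0.0377); its adjusted p was 0.123, 0.108 and 0.127 without control replicate 1, 2 and 3, 0.114 and 0.177 with pseudocounts of 0.1 and 0.01, 0.0715 without a filter and 0.0636 with TPM (2.11e-05 to 0.177 over all alternatives), and the authors' deposited q was 0.47, so its fall is uncertain. Stfa2, Stfa3 and Sprr2a2 belong to families of similar genes, so their values are uncertain.

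Across all genes, 1864 of 10400 passed, of which 1251 (67.1%) were higher and 613 lower in the knockdown; 47 higher and 54 lower genes changed at least 2-fold. At an unadjusted p under 0.05 there were 3611. The 3 values of each group did not overlap in 43.5% of tested genes, against 10% expected by chance for a single gene. Genes are not independent of each other, so the share over all genes can lie far from 10% by chance. The number of genes called changed when 1 library was left out. It was 504, 649 and 469 without control replicate 1, 2 and 3. Without knockdown replicate 4, 5 and 6 it was 2958, 2633 and 721. Those higher and lower were 335 and 169, 428 and 221, and 310 and 159 without control replicate 1, 2 and 3. Without knockdown replicate 4, 5 and 6 they were 1901 and 1057, 1550 and 1083, and 470 and 251. In each of these fits 0 of the genes called with all libraries turned direction, though the fits share libraries. Leaving out a library also leaves fewer degrees of freedom, so a lost call need not be due to that library. The split into higher and lower genes depended on the scaling, with 76.4% higher after scaling to TPM and 52.8% after centring on library medians. In the authors' deposited table, 1924 of all 15917 genes had a q-value under 0.05, of which 1032 were higher and 892 lower. Of the 10400 genes tested in limma it called 1790, with 992 higher and 798 lower. Of those tested, 270 were called only by the authors and 344 only by limma. Among the genes tested in limma, 965 were called higher and 555 lower by both, against 119 and 47.0 for independent lists, and 0 were called in opposite directions; both use the same libraries.

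Knockdown replicate 4 stood apart from the other libraries. Its lowest correlation with a library of its own group, across genes, was 0.982, with knockdown replicate 5. Knockdown replicates 5 and 6 correlated at 0.996, and control libraries at 0.996 or more with each other. Knockdown replicate 5 correlated at 0.9879 to 0.9885 with the controls, more than with knockdown replicate 4. Knockdown replicate 6 correlated at 0.9890 with knockdown replicate 4 and at most at 0.9877 with a control. The first principal component held 69.0% of the variance, with knockdown replicate 4 at 32.5, the other knockdown libraries at 2.85 and 10.8, and the controls between -19.7 and -11.3. Log2 fold changes rose with transcript GC content (Spearman rho 0.511 across genes, which are not independent replicates; 0.267 without knockdown replicate 4). Among the 2050 genes of lowest GC content 37 rose and 176 fell, and among the 2049 of highest GC content 444 rose and 60 fell. After a GC correction, chosen after seeing the data, the median log2 fold change was 1.21 for SREBP2 targets, 0.42 for lysosomal genes and -0.46 for interferon-stimulated genes. After it those that rose and fell were 34 and 1 in the lysosome list, 0 and 23 in the interferon list, 8 and 1 among NRF2 targets, 7 and 1 in sterol transport, 5 and 4 in the NF-kB list, 5 and 8 in the angiogenesis list, 5 and 9 in the TGF-beta list, 1 and 4 in both the matrix and the glycolysis list, 3 and 2 among unfolded protein response genes, 0 and 3 among cell cycle genes and 0 and 2 in oxidative phosphorylation. Without knockdown replicate 4, 23 SREBP2 targets and 33 lysosomal genes rose and 23 interferon-stimulated genes fell.

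**Figure D3:**
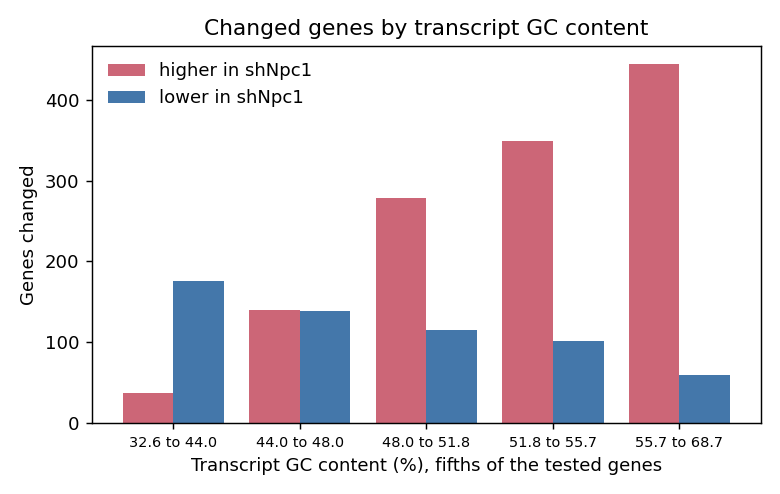
Number of genes called higher (red) or lower (blue) in the knockdown (vertical axis, from 0) in 5 bins of the tested genes of nearly equal size by transcript GC content in percent (horizontal axis). Higher genes go from 37 in the lowest to 444 in the highest bin, and lower genes from 176 to 60.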

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

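No paired analysis was possible because the control and knockdown samples share no replicate numbers. Corrections for GC content and length, the GC slope as a covariate and gene-by-gene weights were chosen after seeing the data; the other settings were planned. DESeq2 was not run, since the table holds no counts. Among the 102 named genes past the threshold, Npc1 not counted, all kept their direction in every setting that tested them. Of these, 73 passed in every fit with 1 library left out and 98 after the GC correction. Most were named for their values in these same libraries, so a kept direction was nearly fixed in advance and is no independent support. A filter of 5 FPKM left Npc1 and the LXR list untested. Npc1 passed in the other limma fits, with log2 fold changes of -3.04 to -1.78. Without 1 library, 469 to 2958 genes passed, 310 to 1901 of them higher and 159 to 1083 lower; fewer samples leave fewer degrees of freedom, and the cause of the rises was not tested. With a 2-fold threshold 101 genes passed (47 higher, 54 lower); the authors' deposited table gives 289 over all its 15917 genes and on its own log2 ratios, so the counts cover different genes and scales. Sample weights gave 7351 genes (4165 higher, 3186 lower), but their estimation did not converge and gave knockdown replicate 6 a weight of 226 and replicate 4 one of 0.0548, so this count is not usable; gene-by-gene weights gave 4977 (2969 and 2008). The GC correction gave 1210 lower genes and 1031 when library levels were kept; with length added 3013 genes passed, 1438 of them lower; with the GC slope as a covariate 4188 (2700 higher, 1488 lower) and 14 lists; with the GC correction without knockdown replicate 4, 3378 (1656 lower). The cause of these differences was not tested. The share of higher genes was 57.4% with trimmed mean of M values, 58.8% with quantiles and 53.3% with the GC correction. With an estimated correlation 2 of the 9 list calls were kept, and the lysosome list (median 0.413) lost its call (adjusted p = 0.264); fry, which tests a list without comparing it with other genes, called 17. Turned directions were all in results that had not passed at first, and their cause was not tested; with the GC covariate oxidative phosphorylation, Tjp1 and Mki67 passed in the turned direction. In camera the direction of the LXR list turned to higher at median log2 fold changes of 0.089 and 0.0896 (pseudocounts 0.1 and 0.01), 0.104 and 0.0829 (both weights), 0.0953 (GC covariate) and, within 0.0636 to 0.1 without 1 library, without control replicate 1 and knockdown replicates 4 and 5 but not without the others. The NF-kB list turned at -0.0445 without a filter and with one of 0.1, -0.0358 with TPM and -0.0219 without trend and in fry, the matrix list at 0.03 in fry, and angiogenesis at 0.118 with the GC covariate. Oxidative phosphorylation, at -0.00877 to 0.162 without 1 library, turned at -0.0673 with the GC covariate (adjusted p = 0.000824), -0.0567 with the GC correction without knockdown replicate 4 and -0.00877 without that replicate, and glycolysis, at -0.0352 to 0.00879 without 1 library, turned without knockdown replicate 5. Plvap, at -0.0766 to 0.0371 without 1 library, turned without control replicate 2 (0.00851) and knockdown replicate 5 (0.0371) or 6 (0.00761), Mcam at -0.0287, -0.0172 and -0.0376 with the GC corrections, and Tjp1 (0.145, adjusted p = 0.0313, the range over all alternatives being 0.0313 to 0.999) and Mki67 (0.242, adjusted p = 0.0407, 0.0055 to 0.922 over all alternatives) with the GC covariate. Absolute depth is unknown, which limits statements on genes listed near 0.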

Other observations

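The tests in this part were chosen after the results were seen, except the share of higher genes without knockdown replicate 4, whose bounds were written before that value was seen. Genes of the vacuolar ATPase, which acidifies lysosomes, rose, among them Atp6v0e2 (2.30-fold) and Atp6v0d1 (1.87-fold). This family was picked from 26 families of gene names that were looked at. Of its 17 tested genes 12 rose and 0 fell, against 11.9% higher among other genes (Fisher's exact test, two-sided, adjusted over 52 tests, p = 1.57e-06), and 12 rose after the GC correction and 10 or more under every other scaling run. Without control replicate 1, 2 and 3 those that rose were 3, 5 and 3, and without knockdown replicate 6 they were 4, while the median log2 fold change lay between 0.335 and 0.436 without any 1 library. The lysosome list holds 6 of the 17, of which 5 rose, so the results overlap in part. Fisher's exact test treats genes as independent, which genes of a family need not be. The lysosome list had an estimated inter-gene correlation of 0.269 and lost its camera call with it (adjusted p = 0.264). The Fisher p-values of this and the other name families may therefore be too small. These tests were also chosen after the results were seen, and the adjustment over 52 tests does not cover that choice. The p-values therefore describe these same calls and are no independent support for any family. In the same set of tests 7 other results passed, of which the one for Stfa names rests on a pair of similar genes already among those with the lowest log2 fold change, so it is not used. Lower genes were more frequent than among other genes for the names Ly6 (4 of 4, adjusted p = 0.000207), Gbp (3 of 3, adjusted p = 0.00265), Ifi (4 of 12) and Itg (4 of 12), both with an adjusted p of 0.0263. Higher genes were less frequent for the names Zfp (9 of 291, adjusted p = 1.81e-06) and Rpl or Rps (2 of 90, adjusted p = 0.0169), against 12.3% and 12.1% of other genes. With the GC corrections and with TPM 1 Itg gene rose, as did 1 Ifi gene with the GC corrections. Without knockdown replicate 4, 2 Itg genes rose and 4 fell. Without knockdown replicate 5, 1 Itg gene and 1 Ifi gene rose. The median of the Zfp genes moved from -0.173 to -0.039 after the GC correction, while the count that rose was 11 of 289. Without control replicate 3 the Ly6, Gbp and Itg genes that fell were 2, 1 and 1; without control replicate 1, 1 Itg gene fell, and without control replicate 2, 2 did. Without knockdown replicate 5 or 6 the Itg genes that fell were 2, and without control replicate 1 or 2 or knockdown replicate 6 the Gbp genes that fell were 2. The Zfp genes that rose were 2 and the Rpl or Rps genes 0 without any 1 control replicate or without knockdown replicate 6, and 2 Itg genes fell with median centring. Members of Ly6, Gbp and Ifi are interferon-induced. Gbp2, Gbp3 and Ifi44 are in the fixed interferon list, so the Gbp and Ifi results overlap with it in part.

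The fall of interferon-stimulated genes may extend beyond the fixed list. A second list of 61 interferon-induced genes was written from background knowledge, but 10 of them had been seen among the results before, so the test was run on the other 51. Of 40 tested, 9 fell and 0 rose (median log2 -0.26; camera p = 7.74e-07, p = 0.00432 with an estimated correlation), and 19 fell and 1 rose after the GC correction. Values for the whole list had been seen when the 10 were removed, so this is a hypothesis, not an independent test.

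Explanations for the fall of the fixed interferon list were weighed. A trend with GC content is argued against, since the median log2 fold change was -0.458 after the GC correction, and so is knockdown replicate 4 as the whole cause, since the median was -0.442 without it. The libraries' mean log2 values over the list were 3.90 to 3.94 in the control and 3.31 to 3.40 in the knockdown. A difference between the cell populations other than Npc1, such as an earlier change in interferon tone, cannot be told apart from the knockdown. Such a difference would coincide with the groups, so no comparison of these libraries can separate it from the knockdown. The labels do not describe independent populations. The exact permutation p was 0.1, the smallest that 3 against 3 samples allow, and concerns only whether the groups differ.

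Whether the dependence of fold changes on GC content comes from libraries or from the knockdown stayed open. Within the control group, replicate 1 differed from replicates 2 and 3 by a GC trend (Spearman rho -0.451 across genes). In size this was weaker than the trend between the groups (0.511). It was stronger than the trend between knockdown replicates 5 and 6 and the controls (0.267). These contrasts set different numbers of libraries against each other, so their sizes are not strictly comparable. Knockdown replicate 4 differed from replicates 5 and 6 more strongly (rho 0.728), but it also had the least Npc1, 6.68% of the control mean against 17.8% and 14.4%, and the labels do not say whether it carried the same hairpin, so a difference between libraries and one in the knockdown cannot be told apart there. Whether a GC trend also made more genes rise than fall stayed open: with a GC correction that kept each library's level 59.8% of changed genes were higher, between the bounds set for either outcome. The full GC correction gave 53.3%, but it also centres the libraries, and centring alone gave 52.8%, so that value decides nothing. On the values as deposited, replicate 4 as the only cause is argued against, since 64.3% were higher without it. The excess of higher genes itself depended on the scaling, and replicate 4 was not left out with median centring. With the full GC correction, which also centres, 51% were higher without replicate 4 and 53.3% with all libraries.

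Gm10487, chosen after its values were seen, was listed at 0 in all 3 control libraries and at 12.6, 8.90 and 6.91 FPKM in the knockdown libraries. A candidate explanation is reads shared between near-identical copies: 14 genes of the table, itself included, had transcripts at least 95% identical to it, and several were listed at 0 in some libraries and above 10 in others. Summed over the copies, the values were 68.7 ± 5.68 FPKM in the control and 63.0 ± 1.37 in the knockdown (SD, n = 3 per group), a ratio of 0.917 with overlapping ranges. No biological explanation was tested.

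Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many changed genes, 1864, and the highest other split gave 0. Every other split mixes control and knockdown libraries, so a difference between the groups widens the spread within its sides. The 0 is therefore no measure of the calls expected by chance. With 10 splits the share cannot be under 0.05.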
